A study of Danio rerio with 3 samples.

How the data were processed

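Single-cell RNA libraries of 3 lanes were used, all from thymi of adult zebrafish that carried an lck reporter with mCherry and a cd79a reporter with eGFP. Live cells negative for both fluorescent proteins had been sorted, which depletes T cells and B cells. 1 pool of 5 fish was dissociated with the enzyme blend Liberase TM and loaded on 2 lanes, which the series text describes as technical repeats, and another pool of 5 fish was dissociated mechanically and loaded on 1 lane. The submitters' processing notes name Cell Ranger 7.0.0 and the genome build GRCz11. The deposited matrices hold raw UMI counts per gene and barcode that the authors had already filtered for barcodes called as cells, and every value in them was checked to be a whole number above 0. Whether intronic reads were counted in these 3 libraries is not given in the sources used here; the series text states it only for the 8 matrices that were re-processed from another series. Those 8 matrices belong to no sample of this series and were not used here.

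Each matrix held 27779 features, and counts of features with the same symbol were added, which left 27083 symbols; genes are named by these symbols. Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs. Scrublet (in scanpy) was run per lane. Its automatic threshold marked 9 of 7066 barcodes (0.127%), and the fallback fixed for that case, a score above 0.25, marked 22 (0.311%), which is still under the 0.5% set as the least credible result, so the caller did not work on these data and doublets were largely left in. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken without mitochondrial genes, ribosomal protein genes and members of the 9 gene lists, and 40 principal components, 15 neighbours and Leiden resolution 1.0 gave the clusters. No correction between lanes was made.

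Clusters were named from 28 marker lists, each written from general knowledge: thymic epithelial, keratinocyte or periderm, muscle, ionocyte, neuroendocrine or neural, ciliated, tuft, enterocyte or hepatocyte, pancreas, mucous or goblet, sensory hair cell, photoreceptor, T cell, B cell, NK or innate lymphoid, macrophage, dendritic, neutrophil, erythroid, thrombocyte, endothelial, fibroblast, pericyte or smooth muscle, Schwann or glia, pigment, cartilage or bone, adipocyte and proliferating. The list of proliferating cells gave no names. A cluster took the name of the list with the most markers among its 100 leading genes, ranked by the ratio of CPM (UMIs of a gene divided by all UMIs, scaled to 1e6) to all other cells. At least 3 markers were needed, and no other list was allowed more markers among the 10 leading genes. A leading gene needed 20 UMIs and a UMI in 10% of the cluster's cells, and a named cluster needed 5 cells. Ties were settled by the 10 leading genes, and a tie of macrophage with dendritic was kept as a combined class. A non-epithelial name was refused where epcam, an adhesion protein of epithelia, reached 500 CPM, and shallow clusters without a marker among the 10 leading genes stayed unnamed. Details of this naming rule (the number of leading genes, the count and detection minimums, the handling of ties and the epcam limit) were settled after the clusters had been seen. The 8 unnamed clusters above the epcam limit held 520 of 4816 liberase cells (10.8%) and 246 of 2228 untreated cells (11.0%). Names are written with the ending -like, since they rest on transcripts alone.

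The shares of classes were compared between the groups as ratios with a 95% interval on the log scale, and shares have exact Clopper-Pearson intervals. Where a group had 0 cells or UMIs, the ratio was computed against a floor of 3 counts over the group and is given as a lower bound. Co-detection was the share of barcodes, thinned to 1000 UMIs, with UMIs of at least 3 genes of a list. Cells of the named epithelial and mimetic classes were clustered again with the same settings. For expression, UMIs were added over a lane or over a class in a lane and given as CPM, with exact Poisson intervals. A list's median log2 ratio was set against 10000 random lists of the same size drawn from genes of similar abundance, and it was called outside their range when it fell beyond the central 95%. Classes were compared within themselves if every lane held at least 50 cells of the class (20 for the epithelial class), and the 4 largest such classes and the epithelial class were used.

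The 9 gene lists were immediate early genes, heat shock, thymopoietic factors, antigen presentation, epithelial and mimetic transcription factors, extracellular matrix and adhesion, inflammatory cytokines and chemokines, interferon response, and apoptosis and p53. Named genes followed a fixed rule. In whole libraries, genes with at least 50 CPM in at least 1 group and both liberase lanes on the same side of the untreated lane were ranked by the smaller of the lanes' log2 ratios, and the 12 highest and 12 lowest were named. Within classes the minimum was 100 CPM, with 6 genes in each direction. For each named epithelial subcluster the rule took the 3 transcription factors or thymopoietic factors with the highest ratio to all other epithelial cells and at least 10 UMIs. Symbols that are only clone identifiers were ranked and counted but not named, and the largest and smallest members of a list were given as examples. Other genes named in the text, such as leading genes of unnamed clusters, were chosen after their values had been seen.

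The 28 marker lists, the 9 gene lists, the cell filter, the comparisons and the rule for named genes were fixed before the data were examined. Alternatives were no cell filter, a stricter one (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, 4000 variable genes, each liberase lane left out, 2 or 4 co-detected genes, no thinning, library sizes scaled by TMM or computed without the 20 most abundant genes, all deposited barcodes, a minimum of 10 CPM and a pseudocount of 10 CPM. Added after seeing the data were the removal of the top 2% of doublet scores, another Leiden seed, shares outside the erythroid-like class, subclusters with the epcam-high clusters, library sizes without erythroid markers, and the ionocyte-like and keratinocyte-like cells as classes of their own.

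The expression steps were tested on simulated data with 23549 genes. The simulated counts had counting error only and no difference between the liberase lanes, whereas the real lanes had a chi-square per degree of freedom of 11.2. Errors were scored after the median log2 ratio of genes with at least 50 CPM had been subtracted, which was not done for the named genes. All 50 genes at each true log2 change of 1, 2 and 4 came out within 0.25, as did 45 of 50 at 6 and 1944 of 1944 unchanged genes. The ranking named 24 of 24 genes simulated with the largest change, and 5 of 5 changed lists and 5 of 100 unchanged lists of 20 genes fell outside the random range. Tools were Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, and edgeR 4.0.16 for TMM factors only. No p-values and no counts of differing genes were computed, because each group is 1 sample. Pathway databases, trajectories and a comparison with other species were left out, as the files give no basis for them.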

Results

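Transcripts were counted in single cells from thymi of adult zebrafish, 13 weeks after fertilization, after a sort for live cells that lacked the fluorescence of the T cell reporter (lck) and of the B cell reporter (cd79a). The liberase group was 1 pool of 5 fish dissociated with an enzyme blend and run on 2 lanes, and the untreated group was another pool of 5 fish dissociated mechanically and run on 1 lane. Each group is therefore 1 sample, and there are no replicates. The way of dissociation cannot be told apart from the pool of fish. All intervals cover counting error only. Liberase lanes 1 and 2 held 2760 and 2486 barcodes with 25824113 and 20935193 UMIs. The untreated lane held 2534 barcodes with 23886452 UMIs. After filtering, 2527, 2289 and 2228 barcodes were left. They had median depths of 8778, 7262 and 6896.5 UMIs and medians of 1517, 1217 and 2054.5 genes. Barcodes with more than 15% mitochondrial UMIs made up 5.40% and 5.95% of the liberase lanes and 11.5% (10.3 to 12.8) of the untreated lane.

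The genes behind the sort were given in every lane before any other. The T cell kinase gene lck had 2.03 and 2.44 CPM in the liberase lanes and 9.59 CPM in the untreated lane. Its reporter mCherry had 1.19, 1.56 and 4.71 CPM. The B cell receptor component cd79a had 1.51 and 2.83 CPM in the liberase lanes and 3.67 CPM in the untreated lane. EGFP had 0.238, 0.390 and 1.77 CPM. These levels rest on 51, 50 and 222 UMIs of lck and on 6, 8 and 41 UMIs of EGFP.

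Which cells each dissociation yielded was the question of the comparison of cell classes. The series text gives the sort as a way to enrich thymic epithelial cells. Erythroid-like cells, which carry hemoglobin, made up 25.7% (24.5 to 27.0) of the liberase cells and 2.83% (2.18 to 3.60) of the untreated cells, a ratio of 9.09 (7.09 to 11.7). Cartilage or bone-like cells made up 4.07% against 0.0449%, that is 196 cells against 1, a ratio of 90.7 (12.7 to 647). Thymic epithelial-like cells numbered 57 (1.18%) against 1 (0.0449%), a ratio of 26.4 (3.65 to 190.3). Their cluster was led by the T cell-attracting chemokine gene ccl25a and carried foxn1, the master regulator of thymic epithelium, and the thymoproteasome gene psmb11a. These 3 genes were its markers of the thymic epithelial list among the 100 leading genes. The pericyte or smooth muscle list had 3 as well, and the tie was settled by ccl25a among the 10 leading genes. Schwann or glia-like cells were 8.17 times (2.56 to 26.1) and fibroblast-like cells 2.99 times (1.59 to 5.62) as frequent in the liberase group, with 3 and 11 untreated cells. Ionocyte-like cells, which transport salts in skin and gills, were 0.319 times (0.229 to 0.445) as frequent, at 1.204% against 3.77%. This class was mixed, as 56 of its 142 cells later fell in an unnamed, mostly untreated subcluster with macrophage markers. The 2 subclusters that kept the name held 10, 16 and 29 cells and 3, 5 and 10 cells in liberase lanes 1 and 2 and the untreated lane.

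Among immune cells, the NK or innate lymphoid-like class was 0.397 times (0.318 to 0.495) as frequent in the liberase group and the T cell-like class 0.570 times (0.486 to 0.670). The neutrophil-like class was 0.601 times (0.526 to 0.688) and the thrombocyte-like class 0.592 times (0.398 to 0.879) as frequent. Of the 2 neutrophil-like clusters, that led by cxcr1 had a ratio of 0.457 (0.385 to 0.543) and that led by lyz a ratio of 0.987 (0.772 to 1.26). A class that carried macrophage and dendritic markers alike made up 15.3% against 10.8%, a ratio of 1.41 (1.23 to 1.62). It was led by xcr1b.1, a chemokine receptor gene of the XCR family. Combined, the 3 macrophage and dendritic classes made up 19.5% against 17.7%, a ratio of 1.102 (0.991 to 1.23). That was not detectable as a difference at this depth. Sensory hair cell-like cells, of the type that senses motion in the ear and lateral line, made up 0.893% against 0.898%, with ratios of 0.617 and 1.41 from the lanes taken alone. Muscle-like cells numbered 9 against 2, a ratio of 2.08 (0.450 to 9.63). All named epithelial and mimetic classes together made up 6.54% against 6.91%, a ratio of 0.946 (0.786 to 1.14). They made up 17.3% against 17.95% with the epcam-high clusters.

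No direction is given for 3 classes, because the alternative settings turned it. Keratinocyte or periderm-like cells had a ratio of 1.46 (1.05 to 2.01) and ran from 0.457 to 1.91 over the settings. Dendritic-like cells had a ratio of 0.634 with a range from 0.589 to 3.29, and macrophage-like cells 0.589 with a range from 0.158 to 1.07. T cell-like and neutrophil-like cells kept their direction, with ranges from 0.206 to 0.746 and from 0.329 to 0.787. The named epithelial classes ranged from 0.498 to 1.24. Ratios were also taken outside the erythroid-like class, which took up much of the liberase lanes. They were 0.519 for NK or innate lymphoid-like, 0.746 for T cell-like, 0.787 for neutrophil-like, 0.418 (0.3003 to 0.581) for ionocyte-like and 1.85 for macrophage or dendritic-like cells. The thrombocyte-like ratio was then 0.774 (0.521 to 1.15) and no longer detectable as a difference. The combined macrophage and dendritic classes, at 1.44 (1.298 to 1.60), and the epithelial classes without and with the epcam-high clusters, at 1.24 (1.03 to 1.49) and 1.26 (1.14 to 1.41), became detectable.

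**Figure D1:**
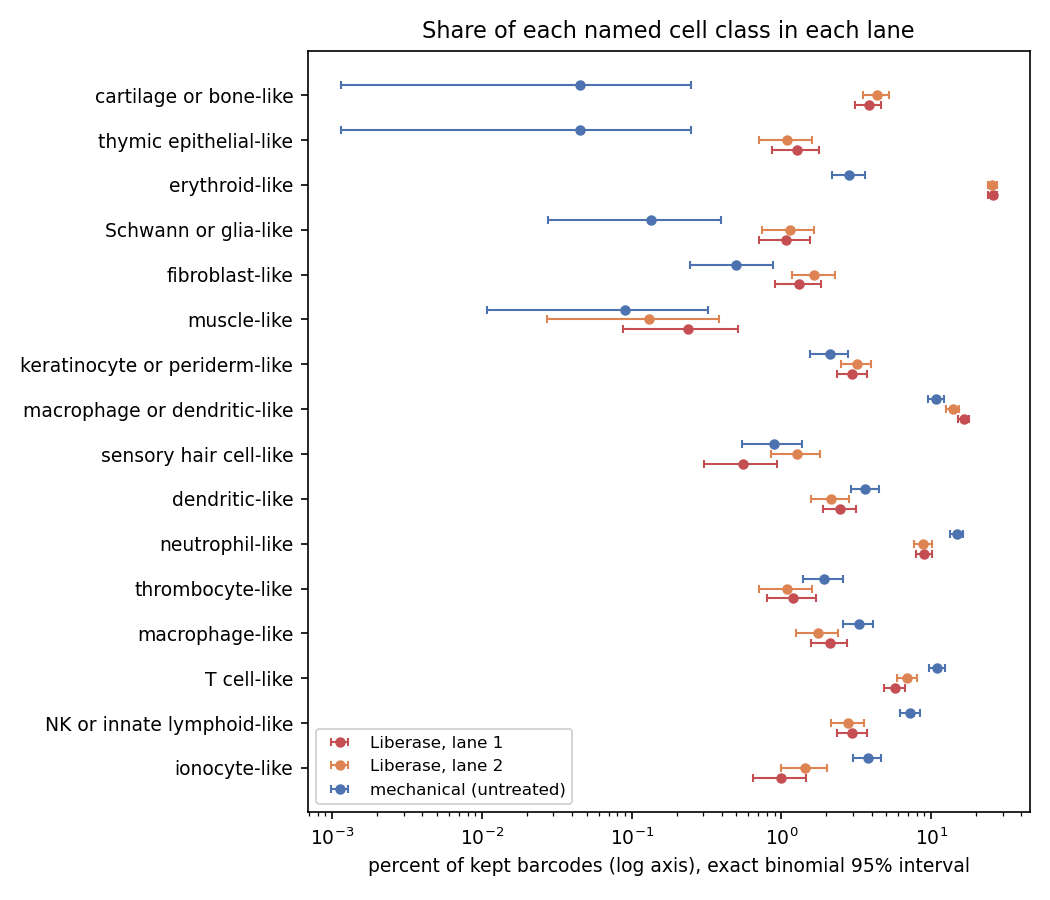
Share of kept barcodes in each named class (percent, log axis) in the 2 liberase lanes and the untreated lane, with exact binomial 95% intervals as bars. Both liberase lanes lie above the untreated lane for erythroid-like (25.7% against 2.83%) and cartilage or bone-like cells (4.07% against 0.0449%) and below it for ionocyte-like cells (1.204% against 3.77%).

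Of 37 clusters, 22 took a name and 15 with 1898 cells did not. The largest unnamed cluster held 4.80% of the liberase and 13.6% of the untreated cells, a ratio of 0.354 (0.3004 to 0.417). It was led by the cathepsin gene ctsbb, the follicular homing receptor gene cxcr5 and tlr9, a sensor of microbial DNA. Another held 83 against 120 cells, a ratio of 0.320 (0.243 to 0.421). It had 10 T cell markers, including lck and cd247, but was led by genes such as the interleukin receptor gene il2rb and the nuclear receptor gene rorc. A small cluster with the type 2 cytokine genes il4 and il13 held 35 against 41 cells, a ratio of 0.395 (0.252 to 0.618). An unnamed cluster with coch, tbx18 and col9a1b, closest to the fibroblast list, held 161 against 50 cells, a ratio of 1.49 (1.09 to 2.04).

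The 8 unnamed clusters above the epcam limit differed in which group filled them. A cluster led by igfbp7 and the basement membrane collagen genes col4a3 and col4a4 held 15 liberase and 70 untreated cells, a ratio of 0.0991 (0.0569 to 0.173). In the other direction, a cluster with the endothelial cadherin gene cdh5 held 70 against 8 cells, a ratio of 4.05 (1.95 to 8.40). This cluster was mixed. Clustered again with the epithelial cells, 12 of its 78 cells formed an endothelial-like subcluster with cdh5 and epcam at 24.4 CPM. Another 35 lay in a subcluster with cartilage markers and epcam at 2318 CPM. Endothelial-like cells were thus counted among the epcam-high clusters. A cluster with the opioid precursor gene penka held 65 against 11 cells, a ratio of 2.73 (1.45 to 5.17). That with the proneural gene neurod1 and the rod pigment gene rho held 175 against 39 cells, a ratio of 2.08 (1.47 to 2.93). It was mixed, so this is not the ratio of 1 cell type. Clustered again with the epithelial cells, 102 of its 214 cells lay in a ciliated-like subcluster (33, 42 and 43 cells in the lanes). Only 10 cells (6, 4 and 0) formed a photoreceptor-like subcluster led by genes such as rho. Intervals included 1 for the clusters with olfactory receptor genes (82 against 42 cells, 0.903), with crp6 and sox8b (49 against 27, 0.840) and with the taste and tuft cell signalling genes gng13a and gnb3a (37 against 23, 0.744). A cluster with grn2 and spic, which encodes a myeloid transcription factor, held 27 against 26 cells, a ratio of 0.480 (0.281 to 0.821).

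Counting cells by joint detection of marker genes needs no clusters, and 4397 liberase and 2093 untreated barcodes were deep enough for it. Erythroid-like cells made up 1035 of the former and 60 of the latter, which lowers the ratios of lists carried by other cells. Ratios outside the erythroid-like cells were not computed. The heat shock list also took up more of the UMIs in the liberase lanes (10.3% and 9.95% against 0.931%), which leaves fewer of the thinned UMIs for other genes. Cells with at least 3 erythroid genes made up 31.7% against 4.63%, a ratio of 6.83 (5.60 to 8.34). Those with 3 cartilage or bone genes made up 5.84% against 1.29%, a ratio of 4.53 (3.06 to 6.71). Fibroblast genes were jointly seen 2.40 times as often in the liberase group. T cell genes were jointly seen in 1.27% against 5.59%, a ratio of 0.228 (0.166 to 0.312). Ionocyte genes were jointly seen in 1.52% against 6.45%, a ratio of 0.236 (0.177 to 0.315). The thymic epithelial list was met in 10.1% against 13.4%, a ratio of 0.756 (0.657 to 0.869). It holds general epithelial genes such as epcam, cdh1 and krt8 besides foxn1 and ccl25a. Lower ratios than 1 were also found for proliferating (0.582), macrophage (0.540), dendritic (0.716), neutrophil (0.680), thrombocyte (0.599) and NK or innate lymphoid cells (0.159), and for B cells (0.0793, 0.00956 to 0.659), with 1 liberase and 6 untreated cells. The liberase cell was in lane 2, and without lane 1 the B cell interval included 1 (0.171, 0.0206 to 1.42). The keratinocyte (0.919) and hair cell (0.971) intervals included 1. Photoreceptor genes were jointly seen in 5 liberase cells and 0 of 2093 untreated cells, which allows joint detection at this depth in up to 0.176%, while a lower expression would go unseen.

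As background, the erythroid genes were jointly seen in 5.19% of T cell-like cells of the liberase lanes and 0.844% of the untreated ones. Dendritic genes were seen there in 4.81% and 7.17%, at median depths of 17038.5 and 17469 UMIs. Ionocyte genes were jointly seen in 0 of 270 and 0 of 237 T cell-like cells. Ratios depended on the depth used. Without thinning they were 1.87 for erythroid, 2.33 for cartilage or bone, 1.59 for fibroblast, 0.587 for ionocyte and 0.420 for T cell genes. The Schwann or glia ratio of 4.76 (1.901 to 11.9) turned to 0.862. The B cell ratio was then 0.343 and that of NK or innate lymphoid cells 0.371. Differences were no longer detectable without thinning for the thymic epithelial (0.949, 0.871 to 1.03) and thrombocyte lists (0.897, 0.799 to 1.01), nor for the former with at least 4 genes (0.840, 0.703 to 1.004). The hair cell ratio lay below 1 without thinning (0.719, 0.631 to 0.820) and with at least 2 genes (0.743, 0.615 to 0.899). With at least 2 genes, the erythroid ratio was 3.66, the cartilage or bone ratio 2.88 and the ionocyte ratio 0.402.

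The epithelial cells were clustered again to ask which cell types they held. The series title concerns mimetic types (thymic epithelial cells that resemble cells of other tissues). Whether the types below are mimetic or came along from tissue near the thymus was not tested. The muscle-like cluster of 11 cells was included by name, with epcam at 280 CPM, under the 500 CPM limit. The 469 cells fell into 11 subclusters, of which 6 took a name. Sensory hair cell-like cells numbered 14, 29 and 20 in liberase lanes 1 and 2 and the untreated lane. They carried the hair cell factor genes gfi1aa at 487 CPM (439 to 539; 246-fold over the other epithelial cells) and atoh1a at 264 CPM (200.1-fold). The cilium regulator gene foxj1a reached 721 CPM (146-fold). Ionocyte-like cells formed 2 subclusters. The smaller (3, 5 and 10 cells) carried the ionocyte factor genes foxi3a at 822 CPM (89.2-fold), foxi3b at 331 CPM (10.5-fold) and gcm2 at 547 CPM (5.38-fold). Over the settings, in the subclusters matched to it, these ran from 368 to 914, from 187 to 335 and from 329 to 568 CPM. The larger (10, 16 and 29 cells) carried the growth factor gene igf2b at 757 CPM (5.47-fold), gcm2 at 417 CPM (4.46-fold) and six4a at 218 CPM (3.70-fold). Muscle-like cells (13, 9 and 3) carried the myogenic factor genes myog at 438 CPM and myod1 at 248 CPM (228-fold), and the growth factor gene tgfb1a at 253 CPM (4.81-fold). The level of tgfb1a ran from 101 to 253 CPM over the settings. The level of myog differed between lanes, at 172, 0 and 3252 CPM, and its 164 UMIs came from 2 of the 25 cells. Of these 25 cells, 16 had lain in a keratinocyte-like cluster. With doublets kept or the epcam-high clusters added, the subcluster that shared most cells with this one was keratinocyte-like, with myog at 0 CPM and myod1 at 27.9 and 25.2 CPM. The muscle-like subclusters of those settings, with 8 and 9 cells, had myog at 1584 and 1391 CPM and myod1 at 531 and 466 CPM. At Leiden resolution 0.5 the levels were 109 and 66.4 CPM.

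Keratinocyte-like cells formed 2 subclusters as well. The larger (29, 26 and 18 cells) carried the chemokine genes ccl25b at 6447 CPM (15.03-fold), with 4140, 10143 and 3706 CPM in the lanes, and ccl19a.2 at 252 CPM (28.6-fold), with 422, 15.7 and 355 CPM. It also had tp63, the regulator of basal epithelium, at 144 CPM (3.64-fold). The smaller (16, 18 and 7 cells) carried the chemokine gene ccl19a.1 at 232 CPM (8.01-fold), with 160, 110 and 946 CPM in the lanes. Over the settings it held ccl19a.1 at 106 to 232 CPM. It also had the epithelial factor genes ehf at 121 CPM (4.02-fold) and klf5l at 306 CPM (2.92-fold). An unnamed subcluster of 68 cells, most of them untreated (13, 10 and 45), held the tolerance regulator gene aire at 27.2 CPM and the tuft cell regulator gene pou2f3 at 146 CPM. Its closest list was macrophage, with csf1rb, grn1, grn2 and mpeg1.1 among its 100 leading genes, a name refused because epcam reached 3528 CPM. Its median depth of 30500.5 UMIs was the highest of the 11 subclusters. At Leiden resolution 2, 2 subclusters of 36 cells each shared leading genes with it. The first (8, 6 and 22 cells) was named neuroendocrine or neural, with elavl3, scg2b and snap25a. The second (6, 4 and 26 cells) had the macrophage markers. Doublets were largely left in, so for the unnamed subcluster of 68 cells doublets with macrophages cannot be told apart from a cell type of its own. Almost all of the thymic epithelial-like cluster lay in another unnamed subcluster (30, 25 and 1 cells), with the chemokine gene ccl19b at 3029 CPM (23.8-fold) and the cytokine gene il15l at 395 CPM (11.4-fold). Adding the epcam-high clusters gave 1235 cells and 24 subclusters, of which 12 took a name.

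**Figure D2:**
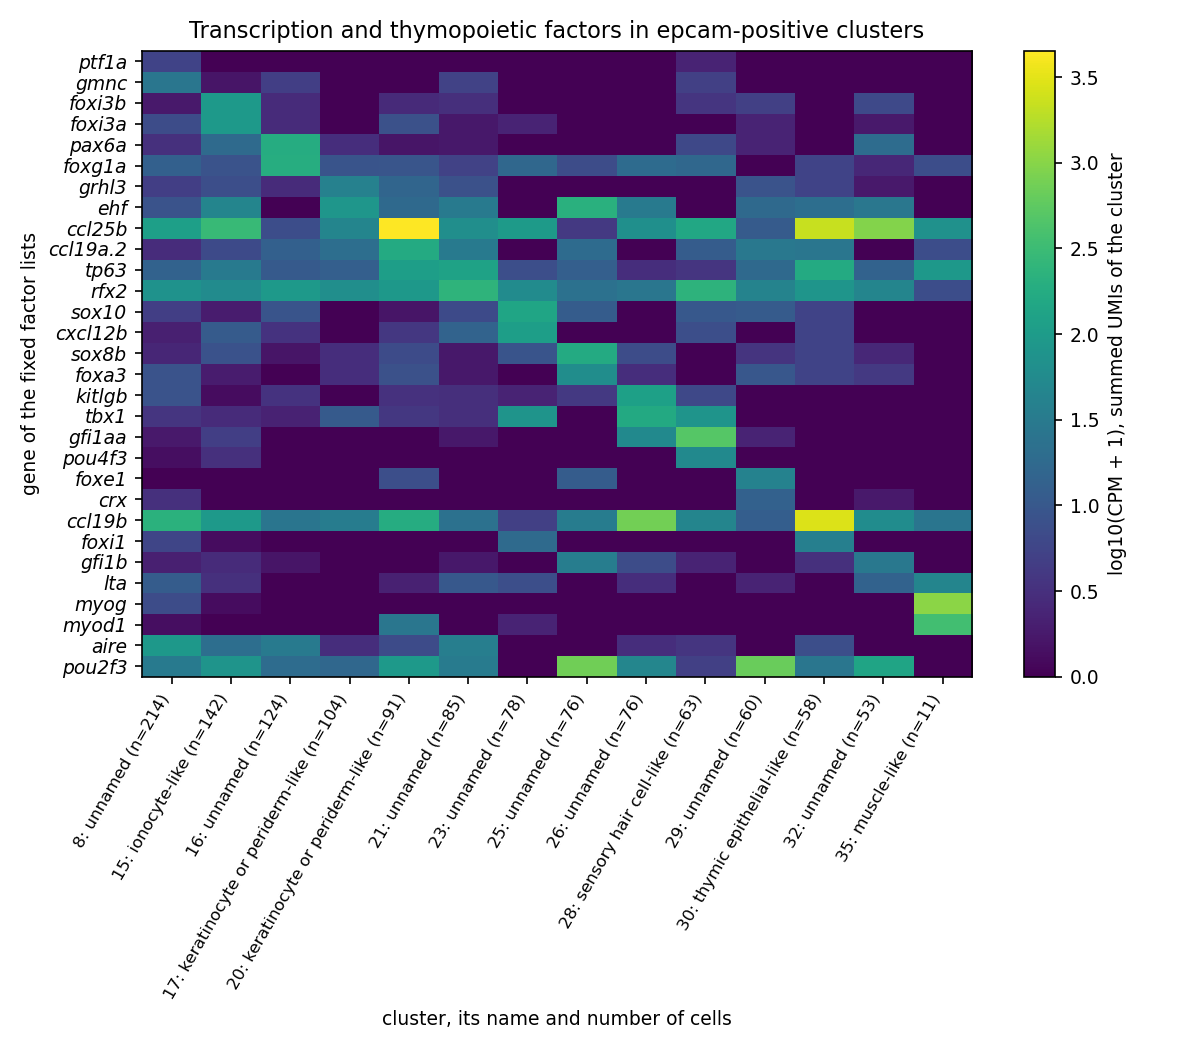
Heat map of transcription factor and thymopoietic genes (vertical axis) in the named epithelial clusters and the epcam-high unnamed clusters (horizontal axis, with numbers of cells), where colour is log10 of CPM plus 1 from the summed UMIs of all 3 lanes. The muscle-like cluster stands out by myog and myod1, the hair cell-like cluster by gfi1aa, and the clusters with gng13a and with crp6 by pou2f3, at 662 and 722 CPM.

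How gene activity in the whole libraries differed between the dissociations was asked next. Of the 12 most strongly higher genes in the liberase libraries, 4 were in the cartilage or bone list and 3 in the heat shock list. The osteocalcin gene bglap, of bone, had 517 against 0.302 CPM (1710-fold, 830 to 4255; 21640, 1988 and 7 UMIs). Its log2 ratio of 10.74 was 8.32 without liberase lane 1. The secreted cartilage protein gene mia had 124 against 0.302 CPM (411-fold, 199 to 1023) and the cartilage proteoglycan gene snorc 88.5 against 0.302 CPM (293-fold). The hypertrophic cartilage collagen gene col10a1b had 123 against 0.389 CPM (316-fold), with a log2 ratio of 8.31 that was 7.65 without liberase lane 1. The cartilage matrix gene matn1 had 611 against 3.37 CPM (181-fold) and fgfbp2b 165 against 0.9504 CPM (173-fold). The cartilage collagen genes col9a1a and col11a2 were 143-fold and 141-fold higher. Among chaperone genes, the small heat shock gene hspb1 had 886 against 3.46 CPM (256-fold, 206 to 323) and hsph1, of the Hsp110 family, 826 against 4.45 CPM (186-fold, 153 to 227). The inducible Hsp70 gene hsp70l had 21907 against 145 CPM (152-fold, 147 to 157) and the co-chaperone gene DNAJA4 2173 against 21.3 CPM (102-fold, 93.4 to 112).

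Of the 12 most strongly lower genes, 6 had only clone names. The sodium-calcium exchanger gene slc8a1b, a marker of ionocytes in the list used here, had 18.9 against 287 CPM (15.2-fold lower). A gene named jac7 had 6.50 against 66.0 CPM (10.15-fold lower), with a log2 ratio of -3.34 that was -2.35 without liberase lane 1 and -5.74 without lane 2. The remaining named genes were the Rac regulator gene arhgap15 at 8.43 against 61.6 CPM (7.31-fold lower) and the ammonium transporter gene rhbg at 24.0 against 169 CPM (7.04-fold lower), besides the ribosome biogenesis gene dkc1 at 14.99 against 89.5 CPM (5.97-fold lower) and the apolipoprotein gene apoeb at 103 against 585 CPM (5.68-fold lower). With a minimum of 10 CPM, 9 of the 12 higher and 4 of the 12 lower genes were among those named.

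Levels in CPM are shares of a total, and 2 gene groups took up much of it. Hemoglobin genes held 13.0% of the UMIs in either liberase lane and 2.198% in the untreated lane, and the heat shock list held 10.3% and 9.95% against 0.931%. The median log2 ratio of all 3058 genes with at least 50 CPM was -0.79, and 0.09 with TMM scaling. Lists are therefore given by how far their median lay above or below that of matched random lists, while the numbers of members higher or lower count the sign of the plain CPM ratio.

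The 28 measured heat shock genes stood out among the 9 gene lists. 24 of them were higher and 4 lower in the liberase libraries, with a median 4.03 above random lists, from hspb1 at a log2 ratio of 8.00 to chordc1b at -1.57. Extracellular matrix and adhesion genes (33 of 56 higher) lay 1.08 above random lists, with the collagen gene col1a1a at 4.80 and col4a5 at -2.23. Thymopoietic factors (20 of 32 higher) lay 1.07 above, with ccl25b at 2.16 and wnt4b at -1.42. Inflammatory cytokines and chemokines (20 of 35 higher) lay 0.89 above, with the interleukin gene il12a at 2.69 and the chemokine gene ccl34b.1 at -2.57. Smaller distances, still outside the random range, were found for immediate early genes (0.44; 22 of 48 higher), epithelial and mimetic transcription factors (0.27; 20 of 62 higher, myod1 at 4.23 and the ciliated cell regulator gene gmnc at -3.62) and antigen presentation (0.21; 4 of 35 higher). Of these, transcription factors lay within the range without liberase lane 2 (0.11), and antigen presentation without lane 1 (0.02) and with TMM scaling (0.17). Interferon response (0.21) and apoptosis and p53 genes (0.29) lay within the range of random lists, but above it without lane 1 (0.31) and without lane 2 (0.32), respectively.

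Of the 28 marker lists, 11 lay above the random range in the liberase libraries, 4 below and 13 within. Those above were cartilage or bone (5.04; 24 of 25 genes higher), erythroid (2.97; 17 of 19 higher, the heme synthesis gene alas2 at 3.25 and fech at -0.70), and fibroblast (2.23; 27 of 29 higher). Pancreas (1.91), photoreceptor (1.51), pericyte or smooth muscle (1.38), Schwann or glia (1.06), muscle (1.04), endothelial (1.01), thrombocyte (0.90) and neuroendocrine or neural markers (0.77) lay above it as well. In the photoreceptor list the rod pigment gene rho had 557 and 445 UMIs in the liberase lanes and 1 in the untreated lane, and in the pancreas list the somatostatin gene sst2 had 250, 1 and 2 UMIs. The muscle list had no fixed direction, since it lay at -0.74 without liberase lane 1 and 1.74 without lane 2. Its parvalbumin gene pvalb2 had 4824, 7 and 1 UMIs in the lanes.

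Markers below the random range were those of ionocytes (-0.68; 23 of 26 lower, slc8a1b at -3.92), T cells (-0.57; 24 of 25 lower, the co-receptor gene cd4-1 at -2.82), ciliated cells (-0.40; 32 of 32 lower) and NK or innate lymphoid cells (-0.39; 21 of 21 lower, the lytic peptide gene nkl.1 at -3.86). The last of these lay within the range without liberase lane 2 (-0.29). Within the range lay mucous or goblet (0.62), sensory hair cell (0.26), neutrophil (0.21), keratinocyte or periderm (0.15), pigment (0.14), thymic epithelial (0.13), dendritic (0.10), adipocyte (0.03), tuft (0.02), enterocyte or hepatocyte (-0.01), macrophage (-0.02), proliferating (-0.07) and B cell markers (-0.36). The thymic epithelial list ran from ccl25a at 1.81 to the tight junction gene cldnh at -1.52. Neutrophil markers lay above the range without liberase lane 1 (0.37), and mucous or goblet markers with all deposited barcodes (0.67). Proliferating cell markers lay at 0.20 without liberase lane 1 and -0.22 without lane 2.

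Comparing the groups inside each class sets aside part of the difference in cell mix, and heat shock genes were higher in the liberase group in all 5 classes. The list's median log2 ratio was 4.71 in macrophage or dendritic-like cells (24 of 26 members higher), 4.38 in neutrophil-like (23 of 25), 3.49 in T cell-like (22 of 24), 3.25 in epithelial (25 of 28) and 2.55 in erythroid-like cells (22 of 24), outside the random range each time. In the added classes it was 3.55 in ionocyte-like and 2.86 in keratinocyte-like cells. The list held 17.1% and 17.04% of the UMIs of macrophage or dendritic-like cells in the liberase lanes against 0.639% in the untreated lane. Hemoglobin genes, which these cells are not known to express, held 0.270% and 0.232% of those cells' UMIs against 0.0386%. Their shares were 0.847% and 0.969% against 0.0948% in neutrophil-like cells and 0.855% and 0.268% against 0.0230% in epithelial cells. The median log2 ratio of all genes moved with TMM scaling from -0.59 to 0.38 in macrophage or dendritic-like, from -0.59 to 0.01 in neutrophil-like, from -0.32 to 0.30 in T cell-like, from -0.30 to 0.24 in epithelial and from 0.11 to 0.31 in erythroid-like cells.

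**Figure D3:**
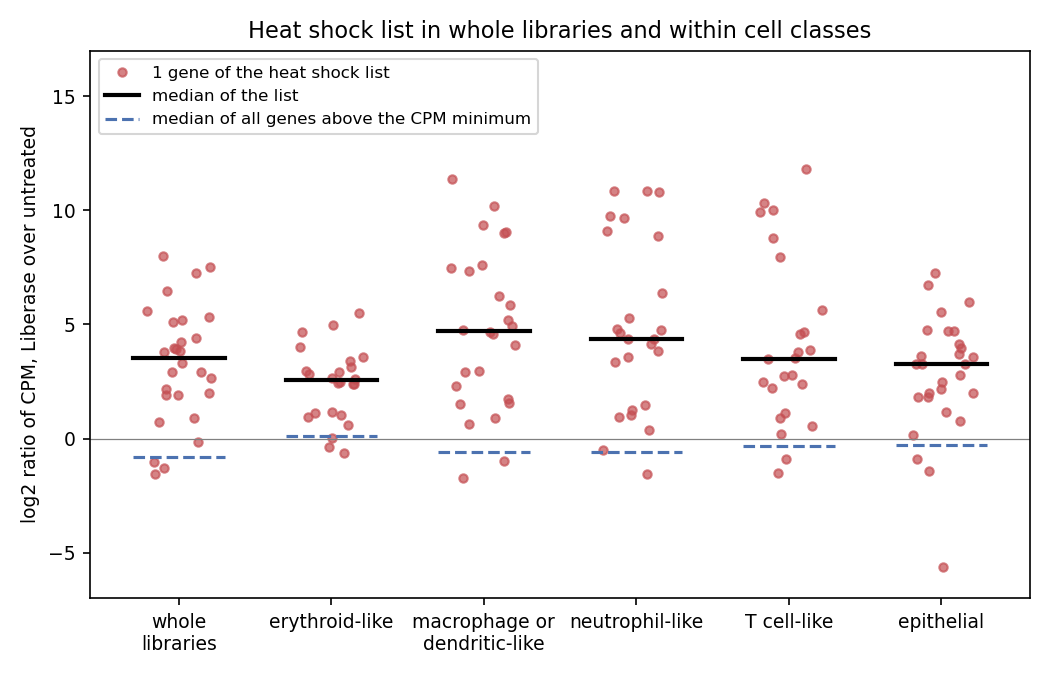
Log2 ratio (liberase over untreated) of the members of the heat shock list in whole libraries and in each of the 5 classes, with 1 point per gene, a solid line for the list's median and a dashed line for the median of all genes above the CPM minimum. Medians of the list lie at 3.55 in whole libraries and between 2.55 and 4.71 in the classes.

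Macrophage or dendritic-like cells (417, 320 and 241 cells) had hsp70l at 39850 against 33.7 CPM (1181-fold), the Hsp90 gene hsp90aa1.2 at 47699 against 89.2 CPM (535-fold) and DNAJA4 at 4199 against 10.04 CPM (418-fold) among the highest named genes. The genes hsph1, hspb1 and bag3, a co-chaperone, had 1, 1 and 3 untreated UMIs and ratios of 2662 (478 to 105138), 650 (117 to 25682) and 519 (178 to 2518). Lower were the ubiquitin ligase gene smurf1 (6.82 against 119 CPM, 17.4-fold), the signalling adaptor gene sh2b3 (9.92-fold), the channel gene trpv1 (8.65-fold), the transporter gene slc12a9 (8.12-fold) and 2 genes with clone names. Neutrophil-like cells (227, 202 and 330 cells) were a different mix in each group, with 237 and 192 liberase against 240 and 90 untreated cells in the clusters led by cxcr1 and lyz. They had hsp70l at 26310 against 14.02 CPM (1876-fold), hsp70.1 at 6325 against 3.51 CPM (1804-fold) and hsp90aa1.2 at 37674 against 47.0 CPM (802-fold). The ubiquitin ligase gene herc4 had 1571 against 2.80 CPM (560-fold), and hsph1 and hspb1 had 1 and 2 untreated UMIs and ratios of 1839 (330 to 72677) and 866 (240 to 7155). Lower in neutrophil-like cells were rgs19, a regulator of G protein signalling (10.8-fold), the autophagy receptor gene optn (9.02-fold), mogs (8.37-fold), usp6nl (6.79-fold), ZNF335 (5.85-fold) and cd83, a surface protein of activated immune cells (5.76-fold).

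T cell-like cells (144, 158 and 245 cells), named for the thymus homing receptor gene ccr9b, the antigen receptor diversifying enzyme gene dntt and zap70, had 6 heat shock genes as highest named genes. These were hsp70l at 15258 against 4.26 CPM (3581-fold, 2293 to 5948), hsp90aa1.2 (1277-fold), hsp70.3 (1052-fold), hsp70.2 (990-fold), hsp70.1 (449-fold) and hsph1 (248-fold). The ribosome biogenesis genes dkc1 (59.3 against 274 CPM, 4.62-fold), ppan (4.21-fold) and pwp1 (3.21-fold) and the splicing factor gene srsf5a (3.45-fold) were lower, along with 2 genes with clone names. In erythroid-like cells (650, 588 and 63 cells) hsp70.2 was at 451 against 10.1 CPM (44.7-fold, 21.7 to 111), hsp70l 31.5-fold, hsp90aa1.2 25.2-fold, hsp70.3 16.1-fold, the co-chaperone gene dnajb1b 10.4-fold and the ubiquitin gene UBB 9.68-fold higher. The hemoglobin genes hbaa2 (770 against 4585 CPM, 5.96-fold) and hbba2 (4.39-fold), the heme synthesis gene uros (1.83-fold), the mitochondrial iron importer gene slc25a37 (1.81-fold), dedd1 (1.70-fold) and ap2m1a (1.65-fold) were lower.

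Epithelial cells (152, 163 and 154 cells) differed in make-up between the groups: 148 of the liberase cells were keratinocyte-like and 58 ionocyte-like, against 47 and 84 of the untreated cells. Thymic epithelial-like cells numbered 57 against 1. The genes hsph1 (677 against 4.37 CPM, 155-fold), hspb1 (105-fold), hsp70l (63.3-fold), herc4 (56.5-fold) and hsp90aa1.2 (46.7-fold) and 1 gene with a clone name were highest. The cholecystokinin gene cckb (3.90 against 202 CPM, 51.9-fold), the progranulin gene grn2 (23.4-fold), the heme oxygenase gene hmox1a (13.8 against 262 CPM; a log2 ratio of -4.25 that was -5.36 without liberase lane 1), nol4la (12.9-fold) and 2 genes with clone names were lowest. Taken separately, ionocyte-like cells had hsph1 289-fold, herc4 99.96-fold, bag3 77.9-fold, hsp70l 71.9-fold, hsp90aa1.2 58.6-fold and DNAJA4 47.5-fold higher, and cckb 83.2-fold, hmox1a 46.9-fold, grn2 46.9-fold and s100t 28.8-fold lower. The UMIs of cckb were 0, 4 and 590 in the lanes, and its log2 ratio of -6.38 was -5.38 without liberase lane 1. That of s100t, -4.85, was -5.43 without lane 2. The ionocyte-like class was itself mixed, as 56 of its 142 cells lay in the unnamed subcluster of 13, 10 and 45 cells, which had grn2 among its 100 leading genes. Keratinocyte-like cells had hsp90aa1.2 121-fold and hsp70l 78.3-fold higher. The genes hsp90aa1.1, hspb1 and hsph1 had 0 untreated UMIs there and were at least 181-fold, at least 114-fold and at least 95.1-fold higher. The collagen-modifying enzyme gene p4ha2 was 69.0 times as high (12.2 to 2740, with 1 untreated UMI), while calb2a was 42.2-fold (a log2 ratio of -5.40 that was -6.71 without liberase lane 1) and scpp8 33.2-fold lower.

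Other gene lists differed by class. In T cell-like cells, 7 of 9 lists lay above the random range. Besides heat shock, these were inflammatory cytokines and chemokines (2.46 above; 18 of 20 higher, the chemokine gene ccl35.2 at 4.28 and the colony-stimulating factor gene csf3a at -4.17) and thymopoietic factors (2.28; the Notch ligand gene jag1b at 4.17). They were joined by immediate early genes (1.28; 43 of 47 higher, the stress sensor gene gadd45bb at 2.61), extracellular matrix and adhesion (0.74), apoptosis and p53 (0.72; the cell cycle inhibitor gene cdkn1a at 1.62) and antigen presentation (0.44; 0.24 and within the range with doublets kept). In macrophage or dendritic-like cells, 6 lists lay above it, with thymopoietic factors at 1.51, inflammatory genes at 1.26 (22 of 26 higher; ccl34b.1 at -4.42), immediate early genes at 0.96 (35 of 47 higher), extracellular matrix at 0.56 and antigen presentation at 0.18. The last 2 lay within the range without liberase lane 2 (0.22 and 0.15), and antigen presentation also with TMM scaling (0.16) and a pseudocount of 10 CPM (0.15). The interleukin gene il12a had 0 untreated UMIs in that class, which sets its log2 ratio at 5.26 at least. Epithelial cells had thymopoietic factors at 1.16 (the chemokine gene cxcl12a at 2.45), inflammatory genes at 0.81 (0.48 without liberase lane 1) and extracellular matrix at 0.56. In ionocyte-like cells alone these 3 lists lay within the range (0.31, 0.48 and 0.06), with inflammatory genes at -0.91 without lane 1 and 0.82 without lane 2. Antigen presentation lay below it there (-0.32; -0.18 and within the range without lane 2). Keratinocyte-like cells had the 3 lists above it (1.14, 0.49 and 0.69), and interferon response as well (0.59). Of these, inflammatory genes (0.24) and interferon response (0.32) lay within the range without lane 2. Erythroid-like cells had immediate early genes at 0.33 (0.19 and within the range without lane 2). Neutrophil-like cells had no list outside the range besides heat shock, but inflammatory genes lay above it without lane 1 (0.49). Epithelial and mimetic transcription factors lay within the range with both lanes, but above it in T cell-like (0.92) and epithelial cells (0.34) without lane 1 and in macrophage or dendritic-like (0.64) and neutrophil-like cells (1.48) without lane 2. With a pseudocount of 10 CPM, inflammatory genes, thymopoietic factors and extracellular matrix lay only 0.56, 0.48 and 0.15 above random lists in T cell-like, 0.77, 0.37 and 0.09 in macrophage or dendritic-like and 0.56, 0.48 and 0.20 in epithelial cells, still outside the range. Hemoglobin genes held 0.172% and 0.193% of T cell-like UMIs in the liberase lanes against 0.0202% in the untreated lane, a sign of free RNA or doublets. Whether transcripts of other cells add to the extracellular matrix, thymopoietic and inflammatory lists in these classes was not tested. Whether the classes differ from each other was not tested either.

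The 2 liberase lanes were compared to show how far repeats of 1 cell suspension differ. Across genes, which are not independent replicates, log2 CPM had a Pearson correlation of 0.983 between them and of 0.902 and 0.904 with the untreated lane. The median absolute log2 ratio was 0.139 between the liberase lanes, and 0.778 and 0.731 against the untreated lane. Erythroid-like shares gave ratios to the untreated lane of 9.10 and 9.08, and T cell-like shares 0.518 and 0.628. The liberase lanes differed from each other by more than counting error alone, with a chi-square per degree of freedom of 11.2, against 435 and 408 for each of them with the untreated lane.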

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

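Chosen only after the results were seen were the removal of the top 2% of doublet scores, another Leiden seed, shares outside the erythroid-like class, subclusters with the epcam-high clusters, library sizes without erythroid markers, and ionocyte-like and keratinocyte-like cells as classes of their own. No paired analysis was possible because no pool of fish was dissociated both ways. Where a difference was detected (an interval without 1, or a list outside the random range), direction was kept by 132 of 145 share ratios, 66 of 67 co-detection ratios, 114 of 114 list medians within classes and 109 of 110 in whole libraries, and by 348 of 348 log2 ratios of named genes within classes and 120 of 120 in whole libraries. The rule for named genes asks for the same direction in both lanes, so leaving out a lane could not turn them. A pseudocount added to both groups could not turn them either. All named genes were counted here without a check of their intervals, and they were picked as the most extreme ratios of these data, so their kept direction says little. Where none was detected, direction changed in 14 of 54 share ratios, 8 of 37 co-detection ratios, 18 of 147 list medians within classes and 18 of 75 in whole libraries. Factor levels have no direction, and 29 of 72 moved, with myog and myod1 in the subcluster matched to the muscle-like one at 0 to 438 and 25.2 to 248 CPM. TMM scaling and the other changes of library size shift the log2 ratios of all genes alike. They could thus hardly change how far a list lay from random lists, so list medians that kept direction under them say little. The heat shock list lay between 4.00 and 4.07 above random lists in whole libraries, and the erythroid-like ratio between 6.62 and 9.60. For the changes below the cause was not tested.

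Without a cell filter the share ratio was 0.550 for keratinocyte-like cells (reversed), 0.498 for named epithelial classes and 0.817 with epcam-high clusters. With the stricter filter it was 0.318 for NK or innate lymphoid-like, 0.206 for T cell-like, 1.44 for dendritic-like (reversed), 6.62 for erythroid-like, 0.457 for keratinocyte-like (reversed) and 1.26 for all mononuclear phagocyte-like cells, and 0.642 and 1.09 for epithelial cells without and with the epcam-high clusters. Keeping doublets reversed dendritic-like (1.22) and macrophage-like cells (1.07). Leiden resolution 0.5 reversed dendritic-like (1.22) and keratinocyte-like cells (0.639) and moved named epithelial classes to 0.679. Resolution 2 gave 0.299 for NK or innate lymphoid-like, 0.278 for T cell-like, 1.03 for dendritic-like (reversed), 0.764 for neutrophil-like and 0.947 for mononuclear phagocyte-like cells. With 4000 variable genes the values were 0.286, 0.458, 3.29 (reversed) and 0.329 for the first 4 of these, 0.657 for keratinocyte-like (reversed) and 0.158 for macrophage-like cells. Removing the top 2% of doublet scores gave 0.278 for T cell-like, 1.23 for dendritic-like (reversed), 0.669 for keratinocyte-like (reversed) and 0.711 for named epithelial cells, and another seed 1.22 for dendritic-like cells (reversed). Outside the erythroid-like class, where a smaller total raises every ratio, the values were 0.519 for NK or innate lymphoid-like, 0.746 for T cell-like, 1.85 for macrophage or dendritic-like, 0.787 for neutrophil-like, 1.44 for mononuclear phagocyte-like and 1.24 and 1.26 for epithelial cells without and with the epcam-high clusters.

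With at least 2 genes, co-detection ratios were 0.402 for ionocyte, 3.66 for erythroid and 2.88 for cartilage or bone genes. Without thinning they were 0.949 for thymic epithelial, 0.587 for ionocyte, 0.420 for T cell, 1.87 for erythroid, 1.59 for fibroblast, 2.33 for cartilage or bone and 0.862 for Schwann or glia genes (reversed). The muscle list in whole libraries ran from -0.74 to 1.74 above random lists when a liberase lane was left out, with a reversal without lane 1. Adding the epcam-high clusters, which brings in more cells, gave 24 epithelial subclusters in place of 11. Some values could not be had: the macrophage or dendritic-like, muscle-like and thymic epithelial-like names were lost under some settings, and keeping doublets left no such combined class for the comparison within classes. Named genes moved by more than their counting error, with no reversal, in 37 of 60 cases within classes with a pseudocount of 10 CPM, in 28 of 60 within classes and 19 of 24 in whole libraries with TMM scaling, and in 16 of 24 with library sizes without the 20 most abundant genes. The pseudocount took the log2 ratios of hsph1 and hspb1 in macrophage or dendritic-like cells from 11.38 to 6.70 and from 9.34 to 4.70. It took inflammatory genes and thymopoietic factors in T cell-like cells from 2.46 to 0.56 and from 2.28 to 0.48 above random lists.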

Other observations

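Tests chosen only after the result was seen were those of a clustering that misplaced thymic epithelial-like cells (both values), of foxn1 and psmb11a outside that cluster, of the pools and yield, of a different mix of cell types and of shared free RNA for the heat shock genes, and the 614-fold receptor value. With the epcam-high clusters added, the epithelial cells included ciliated-like cells (33, 42 and 43 in liberase lanes 1 and 2 and the untreated lane) with aire at 117 CPM, tuft-like cells with the chemokine gene ccl19a.1 at 873 CPM, neuroendocrine-like cells (11, 7 and 0) and photoreceptor-like cells (6, 4 and 0). A cluster of 124 cells carried epcam at 1402 CPM, aire at 29.7 CPM and UMIs of 239 of the 268 olfactory, trace amine and vomeronasal-type receptor genes in the files. The epcam-high cluster with gng13a carried pou2f3, the regulator of tuft cells, at 662 CPM, and that with crp6 and sox8b carried it at 722 CPM.

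The receptor transcripts were weighed between free RNA, nose tissue and doublets. That cluster held 88.9% (88.4 to 89.3) of all receptor UMIs but 2.35% of all UMIs. The bound set for excluding free RNA, 90%, was narrowly missed, and it was judged too high only after the values had been seen. Receptors had 11217 CPM in the cluster against at most 18.3 CPM in T cell-like, neutrophil-like and erythroid-like cells, 614-fold more. The cluster was picked by its highest share of receptor UMIs, so a higher level was built in, but not its size. That size argues against RNA shared evenly among droplets, while fragments of olfactory neurons in only some droplets stay open. A median of 10.5 distinct receptors per cell at 5000 UMIs (quartiles 5 and 19.25), with 30.8% of receptor UMIs from the top gene, is unlike mature olfactory neurons with a single receptor. Yet ompa and ompb, genes of the olfactory marker protein, reached 218 CPM, above the 100 CPM set as the limit. Both criteria took all receptor families together. With the epcam-high clusters added, 47 cells of this cluster formed a subcluster led by v2r and olfc genes, for which neither criterion was tested. Immature or carried-over olfactory cells thus cannot be told apart from thymic epithelial cells that express the receptors. Doublets also stay open, as median UMIs were 1.34, 2.68 and 1.22 times those of other epithelial cells in the lanes. Receptor expression by thymic epithelial cells may thus be a hypothesis to follow, and no group of the design tests it.

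The thymic epithelial-like cluster held 57 liberase cells and 1 untreated cell. Summed CPM of ccl25a, foxn1, psmb11a and prss16 differed by only 1.22 times (1.15 to 1.29), within the bound for misplaced untreated cells, but that criterion was wrong: of 1978 prss16 UMIs 2 lay in the cluster and 790 in macrophage or dendritic-like cells, and 1 untreated cell held 321 of 382 ccl25a UMIs. Without clusters, 59 liberase cells (1.23%) and 2 untreated cells (0.0898%) had at least 5 ccl25a UMIs, a ratio of 13.6 (3.34 to 55.8), which argues against misplaced cells with that much ccl25a. In whole libraries foxn1 was 2.17 times (1.55 to 3.10) and psmb11a 1.34 times (0.856 to 2.15) as high in the liberase lanes, the latter at 2.201 times (1.396 to 3.55) in lane 1 and 0.282 times (0.104 to 0.661) in lane 2, and 180 of 227 and 72 of 102 UMIs of them lay outside the cluster. Untreated cells with foxn1 or psmb11a but little ccl25a in other clusters thus stay open, since the interval of psmb11a includes 1 and its direction turns between the lanes. Whether the igfbp7 cluster is the untreated counterpart stays open too. Summed CPM of ccl25a, foxn1 and psmb11a was 4424 in the thymic epithelial-like cluster and 255 there, 17.3 times less (15.5 to 19.5), past the bound set against it, but that bound was wrong, since ccl25a, which leads and names the cluster, made up 1956 of the 2033 UMIs. A better release by the enzyme and a difference between the pools cannot be told apart, since all 57 liberase cells come from 1 pool and no pool was dissociated both ways.

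Heat shock genes were higher in the liberase lanes in each of the 5 classes tested. The lowest class median was a log2 ratio of 2.55, against 4.71 in the highest, which a different mix of cell types does not give. A few abundant genes taking up the counts were weighed by TMM scaling, with which the median in whole libraries was 4.27 (2.71 to 5.11). That test could hardly fail, since factors of 0.827 and 0.867 (liberase lanes) and 1.40 (untreated lane) raise every ratio. Hemoglobin and heat shock genes took up more of the counts in the liberase lanes, which lowers the ratios of other genes rather than raising them. Free RNA shared by all droplets would give like levels in all classes, whereas hsp70l in the liberase lanes differed 58.6-fold between macrophage or dendritic-like (39850 CPM) and erythroid-like cells (680.3 CPM). The remaining classes had at least 15258 CPM, so this argues against free RNA as the source outside the erythroid-like class. For that class free RNA stays open. The heat shock list held 0.552% and 0.588% of its UMIs in the liberase lanes against 0.0533% in the untreated lane. Hemoglobin genes held 0.847% and 0.969% of neutrophil-like UMIs in the liberase lanes, so a background of that size is possible. A response of the living cells to the enzymatic dissociation may be the source, as a hypothesis, and handling or condition of the other pool of fish stays open and untested, because dissociation and pool go together.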
